A study of Arabidopsis thaliana with 11 samples.

How the data were processed

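The series holds 11 chromatin immunoprecipitation libraries from inflorescences of soil-grown Arabidopsis thaliana (Col-0), grown with 16 h of light and 8 h of darkness. Per the labels' protocols, tissue was crosslinked in 1% formaldehyde, chromatin was sheared by sonication and precipitated with an anti-FLAG antibody, and libraries were amplified with 15 PCR cycles. That protocol names the FLAG antibody for batch 2 as well, whose titles name RFP; which antibody was used there is not given in the sources used here.

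Per the submitters' processing notes, Trim Galore, Bowtie2, Picard, deepTools 3.0.2, MACS2 2.1.0 and HOMER were used with the TAIR10 genome; their order and settings are not given in the sources used here. The authors deposited 1 peak list for each of 8 libraries, called on single libraries and not on pooled replicates, and 3 merged lists. Each library list gives a score per peak, deposited by the authors and equal to 10 times the -log10 q value. It also gives the fold enrichment, a ratio deposited by the authors as their peak caller computed it, and -log10 of p and q, deposited by the authors. The merged ACD15 and ACD21 lists are unions of both replicates per the file headers, in which 46.2% and 49.9% of the regions come from both. The MBD5/MBD6 list is, per the file headers, a union of broad peaks of MBD5 and of MBD6; 7229 of its 10566 regions have both parents, and no library of this series is a parent. The names of the FLAG lists say that peaks of the control without transgene were taken out, and those of the RFP lists that regions prone to unspecific enrichment were. Gaps in the peak numbering show what share was left: 93.2% and 94.8% for ACD15, 96.7% and 98.7% for ACD21, 53.0% and 96.5% for MBD6-RFP in wild type, and 42.9% and 93.1% in acd15 acd21. Peak lists hold no read depth, so no precision from depth can be given, and the lists of the 3 control libraries are not used here. A region missing from a list is one not called, which can follow from depth as well as from binding.

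Entries with the same start and end, which differ only in their summit, were joined into 1 region with the highest score (6909 entries gave 5661 regions in ACD15 replicate 1, for example). Positions in the library lists were turned from 0-based to 1-based starts. The reference was a TAIR10.1 copy; its nuclear chromosome lengths and the ends of all peaks were checked against each other, and no peak ended beyond its chromosome. Gene models came from its annotation of 37899 genes, 27444 of them protein-coding. This annotation has no transposon features, so the planned test of transposon superfamilies was not run and transposons as such are not analysed here; transposon genes stand among its 4843 pseudogenes. In place of transposon-rich bins, gene-poor bins were used, 200 of 1193 bins of 100 kb with protein-coding exons in under 20% of their bases, a limit chosen after the annotation was seen. Organelle regions, 32 in the MBD5/MBD6 list, were left out of all comparisons.

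Overlap required at least 1 bp on the nuclear chromosomes. Overlaps were set against 1000 placements of the other list shuffled within its chromosomes (one-sided), and CG density and gene context against 1000 width-matched placements (two-sided). The context of a peak was that of its centre, taken in the order protein-coding gene body, pseudogene, promoter of 1 kb, other. GC-matched placements were drawn from 600000 random windows in bins of 1 percentage point of GC content. Genotypes were compared by exact permutation of 2 against 2 libraries (two-sided, smallest p 0.333), and retained with lost peaks by 100000 permutations of peaks. Gene lists were tested with Fisher's exact test (two-sided) on peaks from 1 kb upstream of the start to the gene end, against all other annotated genes. Families of tests were adjusted by the Benjamini-Hochberg method at 0.05. Intervals on shares are 95% exact binomial (Clopper-Pearson) intervals over peaks. P-values against shuffled placements measure only how peaks are placed, and those from permuted peaks only the spread over peaks. The labels do not say whether replicates came from separate plants, so their spread may be technical.

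Named genes were chosen by a fixed rule: all members of the fixed lists with a peak in both replicates of a group, and the complex genes in every library; the 10 protein-coding genes with a symbol and a promoter peak (1 kb upstream to 200 bp downstream) in all 4 FLAG libraries, by mean percentile of the score; up to 10 genes per MBD6-RFP pattern by the same percentile; and the 3 highest regions of each merged list. The 6 fixed lists hold 92 entries, all found in the annotation: promoter-methylated and imprinted genes, genes of the MBD5/MBD6 complex, DNA methylation and silencing genes, abundantly transcribed genes, floral meristem and organ identity genes, and active or heat-responsive transposons. For the complex, 3 of 5 genes held an ACD15 region (adjusted p = 0.353), 3 an ACD21 region (0.155) and 2 an MBD5/MBD6 region (1), by Fisher's exact test. The ACD15 and ACD21 counts include the peak of each FLAG fusion at its own gene, which may come from the transgene. Groups, tests, gene lists, named-gene rule and most alternatives were set before the data were examined; GC-matched placements, peaks limited to MBD5/MBD6 regions and the highest peak number were added afterwards.

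Alternatives were an overlap of at least 50% of the peak and the upper 50% of each list by score. Placements were also kept within gene-poor or other bins. Others were intersections and unions of replicates, equal list lengths of 404 peaks, and joining of peaks within 500 bp. A 200 bp window was set at the summit of library peaks and at the centre of merged regions. Further alternatives were any overlap for context, promoters of 500 bp, a shorter gene window, each replicate left out, and a replicate block. Overlap, CG density and context were tested on simulated data modelled on a list of 3571 regions. Unrelated lists gave p at or under 0.05 in 5.5% of 200 simulations for overlap, and random placements in 7.5% of 200 for CG density. With an overlap of 30% planted, the expected 33.6% was recovered as 33.6%, and a planted CG ratio of 1.38 as 1.37. Lists chosen by GC content alone gave a ratio of 1.20 to width-matched and 0.998 to GC-matched placements. For peaks moved into promoters, an expected 29.3% was recovered as 29.3%. The expected and planted values were counted with the same overlap, density and context definitions, so these matches do not test those definitions. The permutation of peaks was tested on independent normal values and not on peak lists. It gave p at or under 0.05 in 1.0% of 100 simulations without a difference, which does not cover peaks that depend on each other. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used, with seed 1.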

Results

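Chromatin immunoprecipitation followed by sequencing was used to map where ACD15, ACD21 and MBD6 sat on the genome of Arabidopsis thaliana inflorescences. MBD6 is a methyl-CG-binding domain protein, ACD15 and ACD21 are small proteins with an alpha-crystallin domain, and SLN, also named in the series title, is a J-domain protein. The labels describe 11 libraries in 6 groups. ACD15-FLAG, ACD21-FLAG, MBD6-RFP in wild type plants and MBD6-RFP in acd15 acd21 double mutants had 2 libraries each. The controls without a transgene, 1 for FLAG and 2 for RFP, have no peak list used here, so no background value is given for them. Every FLAG library belonged to batch 1 and every RFP library to batch 2, so a difference between the ACD15 or ACD21 lists and the MBD6 lists cannot be told apart from batch. The antibody label reads anti-FLAG for all libraries, although the titles of batch 2 name RFP. Read depth is unknown from peak lists. The lists held 5661 and 10946 regions for ACD15, 6774 and 3571 for ACD21, 3492 and 1244 for MBD6 in wild type, and 3987 and 404 for MBD6 in acd15 acd21, replicate 1 first. A deposited list of 10566 regions bound by MBD5 or MBD6 served as a reference set; its parent lists belong to no library of this series.

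Merged ACD21 regions were nearly all also ACD15 regions, while 5014 of the ACD15 regions had no ACD21 region, and most sites of both lay in the MBD5/MBD6 regions. Of the 6803 merged ACD21 regions, 96.4% overlapped one of the 11101 merged ACD15 regions, against 9.34% for shuffled placements, and 97.7% overlapped an MBD5/MBD6 region, against 13.7%. For ACD15, 94.1% lay in MBD5/MBD6 regions, against 14.6% by shuffling, and 54.8% overlapped ACD21, against 5.84%. Seen from the other side, 70.7% of the 10534 nuclear MBD5/MBD6 regions held an ACD15 region and 47.9% an ACD21 region. All 6 overlaps had the smallest one-sided permutation p that 1000 shuffles can give, 0.001, also after adjustment. With single replicates, the share of ACD21 peaks that overlapped ACD15 was 98.3% without replicate 1 and 70.2% without replicate 2. The share of ACD15 peaks that overlapped ACD21 was 84.6% without replicate 2 and 29.5% without replicate 1, and the MBD5/MBD6 shares fell to 41.8% for ACD15 without replicate 2 and 27.4% for ACD21 without replicate 1.

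Within each FLAG group the shorter list was almost contained in the longer one. In ACD15, 97.2% of replicate 1 peaks overlapped replicate 2 (95% exact binomial interval over peaks 96.7 to 97.6), and 46.9% of replicate 2 peaks overlapped replicate 1. In ACD21, 99.0% of replicate 2 peaks overlapped replicate 1 (98.6 to 99.3), and 50.2% of replicate 1 peaks overlapped replicate 2. Shuffled placements gave between 2.65% and 9.17%, with a one-sided permutation p of 0.001 in all 4 directions, the smallest 1000 shuffles can give. The intervals treat peaks as units and say nothing of the spread between plants. Jaccard indices (bases shared over bases in either list) were 0.389 for the ACD15 pair and 0.470 for the ACD21 pair. Between an ACD15 and an ACD21 list they ran from 0.232 to 0.586. ACD15 replicate 1 was closer to both ACD21 lists (0.586 and 0.484) than to ACD15 replicate 2. ACD15 regions without an ACD21 region therefore cannot be told apart from a difference in list length.

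**Figure D1:**
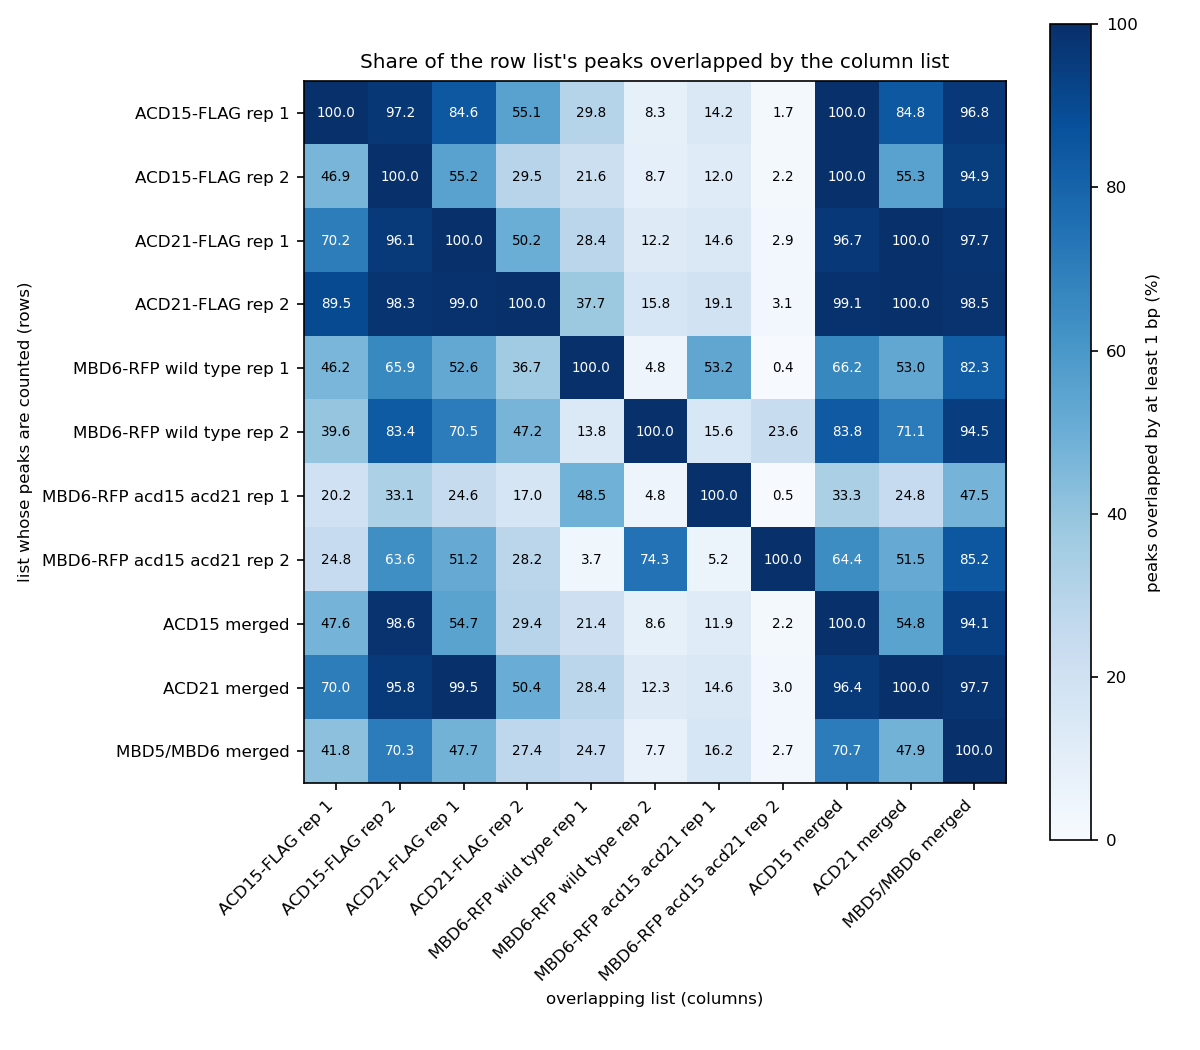
Each cell gives the percent of peaks in the list of its row that overlap the list of its column by at least 1 bp, for 8 libraries and 3 merged lists. ACD15 and ACD21 lists overlap each other and the MBD5/MBD6 regions, while the MBD6-RFP wild type lists share 4.78% and 13.8% of their peaks with each other.

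The highest-ranking regions of the merged lists were found at genes of several kinds. For ACD15 these were chromosome 5, 9982961 to 9984285, at AT5G27950; chromosome 4, 5251969 to 5252805, between AT4G08310 and TPR8; and chromosome 5, 22840800 to 22841635, at AT5G56380. For ACD21 they were chromosome 5, 15183190 to 15184672, at the pseudogene AT5G38037; chromosome 4, 10632407 to 10633750, at AT4G19510; and chromosome 1, 25696435 to 25698739, which lay 184 bp from AT1G68490. Fold enrichment at the first of each set, which is the peak caller's own value deposited by the authors, was 8.60 and 10.4 in the ACD15 replicates and 9.73 and 8.10 in the ACD21 replicates. All 6 lay in MBD5/MBD6 regions.

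A promoter peak in all 4 FLAG libraries was found at 1533 protein-coding genes, 543 of which have a symbol. The 10 with the highest mean rank were TPR8, ACT2, COBL2, SARK, PRP2, XCT, EMB2820, COL3, COL4 and P5CS1. The peak of TPR8, a tetratricopeptide repeat gene, had its summit 267 bp upstream of the start, with folds of 8.31 and 10.2 for ACD15 and 9.16 and 7.33 for ACD21. At COBL2, a COBRA-like gene, the peak lay on chromosome 3 at 11725849 to 11727517, and at SARK, a senescence-associated receptor kinase gene, on chromosome 4 at 14911526 to 14912755. PRP2, a proline-rich cell wall protein gene, and the divergent XCT, a regulator of the circadian clock, shared 1 peak on chromosome 2 at 9062893 to 9064558. Its summit lay 1139 bp from the PRP2 start and 1922 bp from the XCT start, beyond the promoter of both. The COBL2 summit also lay beyond the promoter, 1057 bp from the start and inside AT3G29805. COL3 and COL4, CONSTANS-like B-box genes, had summits 374 bp and 504 bp upstream of their starts, on chromosome 2 at 10566462 and chromosome 5 at 8588953. The peak of EMB2820, an embryo-lethality gene, was on chromosome 5 at 8446120 to 8447364, and that of P5CS1, a proline biosynthesis gene, on chromosome 2 at 16603273 to 16604028. The peaks of all 10 genes overlapped an MBD5/MBD6 region.

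Genes known for promoter methylation or imprinting carried ACD15 and MBD5/MBD6 regions more often than other genes did. Of the 21 genes in this list, 13 held an ACD15 region (61.9%, against 22.1% of other genes), 14 an MBD5/MBD6 region (66.7% against 29.5%) and 8 an ACD21 region (38.1% against 14.0%). The two-sided Fisher exact tests gave odds ratios of 5.72, 4.78 and 3.77 and adjusted p values of 0.0042, 0.00993 and 0.0774 over 42 tests; adjusted over the list alone they were 0.000699, 0.00166 and 0.0129. Of the 8 genes with an ACD21 region, 5 had a peak in both ACD21 replicates. No other list passed at 0.05 after adjustment. With a window ending 200 bp downstream of the gene start, the ACD15 share was 47.6% (Fisher exact test, adjusted p = 0.0703) and the MBD5/MBD6 share 47.6% (adjusted p = 0.206), so neither passed. Without replicate 2 the ACD15 share was 38.1% (Fisher exact test, adjusted p = 0.0484).

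In that list, 8 genes had a peak in both ACD15 replicates and 5 of them also in both ACD21 replicates. FWA, a homeodomain gene silenced by methylation of repeats at its start, held peaks with summits 3 to 26 bp upstream of the start in all 4 FLAG libraries, on chromosome 4 at 13038123 to 13038711 in ACD15 replicate 1, with folds of 2.99, 4.89, 2.69 and 2.21. At ROS1, which encodes a DNA demethylase, the peak lay on chromosome 2 at 15314671 to 15315072, upstream of the start, with folds of 5.15 and 8.10 for ACD15 and 5.16 and 3.41 for ACD21. HDG8, an imprinted homeodomain gene, had upstream peaks on chromosome 3 near 760392 in all 4 FLAG libraries and in MBD6-RFP replicate 1 of both genotypes. In RPP7, a disease resistance gene, the peak lay in an intron on chromosome 1 at 21758378 to 21759524, with ACD21 folds of 8.44 and 5.09. The BNS peak had its summit beyond the gene end, in AT1G73175, on chromosome 1 at 27514879 to 27516634. QQS, a starch-related gene, with an upstream summit, and HDG9 and SNC1, with summits in coding exons, had peaks in both replicates of ACD15 but not of ACD21; QQS also had one in ACD21 replicate 1 (fold 2.11). In MBD6-RFP, HDG8, AGL36 and SNC1 held a peak in wild type replicate 1 and HDG9, HDG8, AGL36 and FLC in acd15 acd21 replicate 1; AGL36 and FLC are named here after their values were seen.

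The genes of the complex itself carried peaks that differed with the transgene. ACD15 held a 2124 bp peak in ACD15-FLAG replicate 1, on chromosome 1 at 28682362 to 28684485, with folds of 7.65 and 9.26 in the replicates, and no peak in any other group. ACD21 held a 2111 bp peak in ACD21-FLAG replicate 1, on chromosome 1 at 20453893 to 20456003, with folds of 8.66 and 6.82, and none from 1 kb upstream to the gene end in the other groups. Neither region overlapped an MBD5/MBD6 region. In each, 1 end of the peak lay near the end of the coding sequence, at 28682371 in ACD15 and 20455994 in ACD21. The complex genes were listed as a check for the transgenes. Peak lists cannot tell reads of a transgene from binding at the native gene, so these 2 peaks are not read as binding. MBD5, which encodes the paralogue of MBD6, had a peak upstream of its start in all 4 FLAG libraries, on chromosome 3 at 17147081 to 17147565 in ACD15 replicate 1. SLN had one in ACD15 replicate 2 and ACD21 replicate 1, and MBD6 in none of the 8 libraries.

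**Figure D2:**
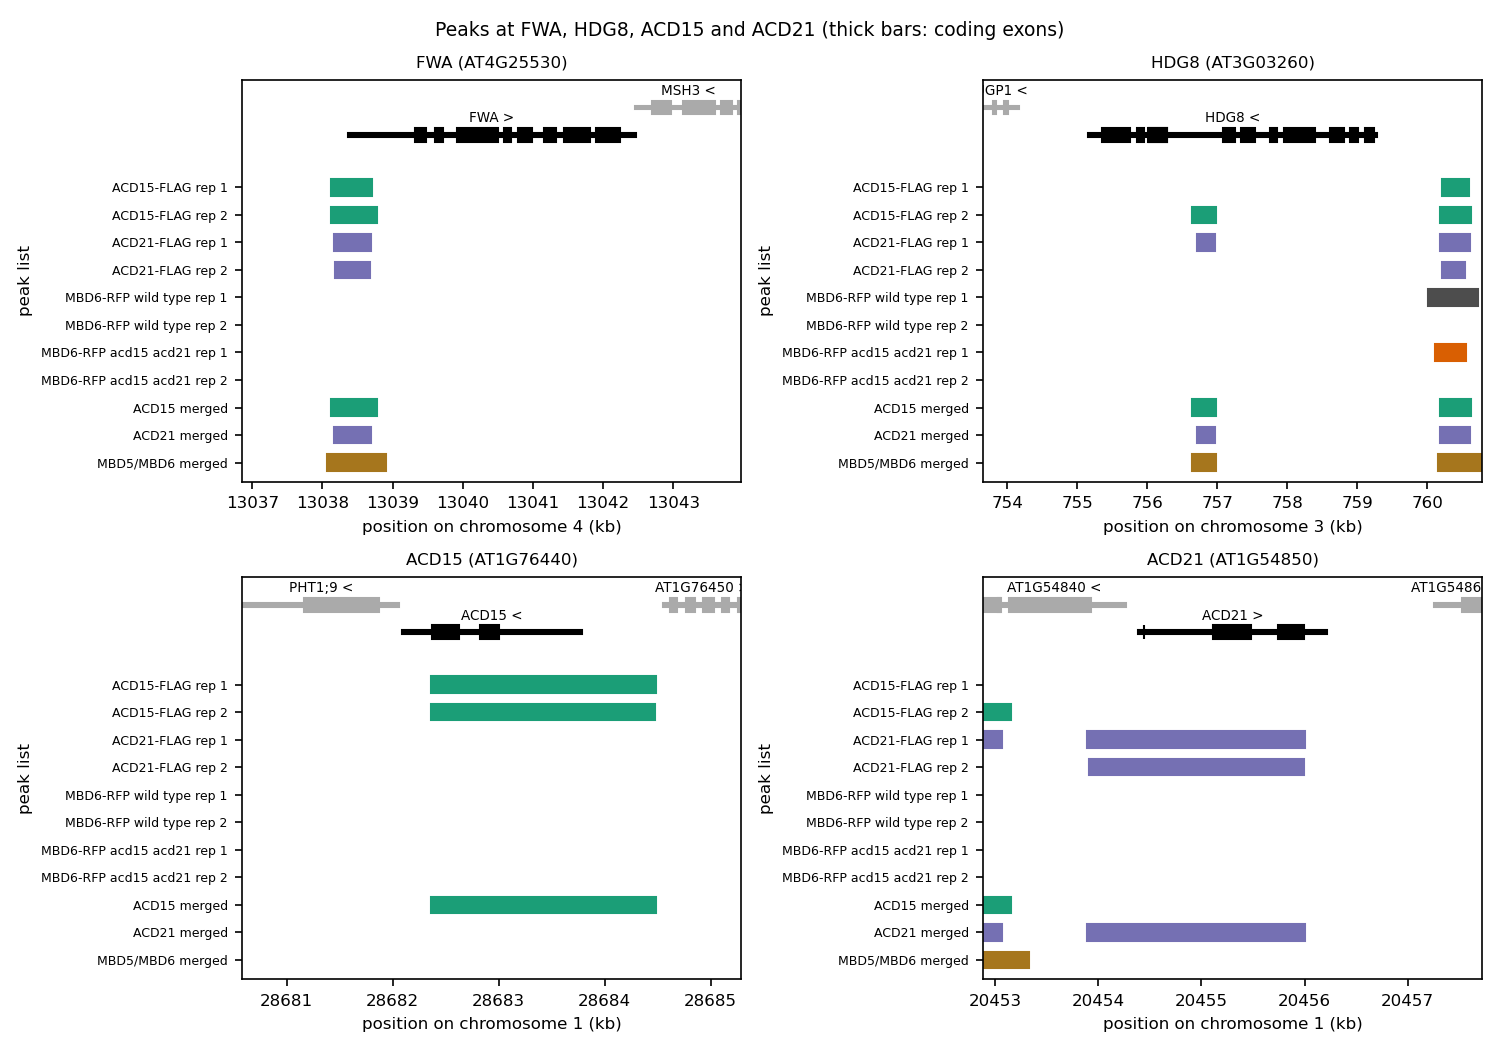
Horizontal bars mark peaks along the chromosome position in kb at FWA, HDG8, ACD15 and ACD21, 1 line per list, with gene models on top and coding exons thick. The ACD15 and ACD21 genes carry a long peak only in the lists of their own FLAG fusion, and FWA in the FLAG lists and the MBD5/MBD6 list.

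Among 21 DNA methylation and silencing genes, 6 held an ACD15 region, 5 an ACD21 region and 8 an MBD5/MBD6 region, and none of these shares passed against other genes (adjusted p = 1, 0.857 and 1, Fisher exact test). NRPE1, the largest subunit of RNA polymerase V, and SUVH5, a histone methyltransferase, had upstream peaks in all 4 FLAG libraries, at chromosome 2, 16713717 to 16714280 and 14822178 to 14822536. DCL3, which cuts small RNA precursors, and VIM1, a methyl-CG-binding cofactor of maintenance methylation, had upstream peaks in both ACD15 replicates, at chromosome 3, 15752951 to 15753196 and chromosome 1, 21418452 to 21418765, and in ACD21 replicate 1 (folds 1.80 and 2.83); NRPD1 (ACD15 replicate 2 and ACD21 replicate 1) and MET1 (ACD15 replicate 2), named after their values were seen, complete the 6. Of 20 abundantly transcribed genes, 4 (ACT2, ACT7, UBC21 and EF1A) held an ACD15 region and 2 (ACT2 and UBC21) an ACD21 region, and 8 an MBD5/MBD6 region (Fisher exact test, adjusted p = 1, 1 and 0.969). ACT2, an actin gene, had a peak at percentiles 99.2 to 100 of the FLAG lists, with the summit in the 5' UTR, on chromosome 3 at 6474082 to 6475634. Of 20 floral meristem and organ identity genes, PI and TFL1 held an ACD15 region, and TFL1 alone an ACD21 or MBD5/MBD6 region (Fisher exact test, adjusted p = 0.908, 0.969 and 0.136). The peak at TFL1, a repressor of floral fate, had its summit 712 bp upstream of the start, on chromosome 5 at 1026378 to 1027104, and MBD6-RFP replicate 1 lists of both genotypes held a peak there, at percentile 91.8 of the wild type list (fold 13.6) and 2.62 of the acd15 acd21 list (fold 2.38). Of 5 active or heat-responsive transposon genes, the 3 copies of ONSEN, a heat-activated retrotransposon, held an ACD15 and an ACD21 region, and these and EVD an MBD5/MBD6 region (Fisher exact test, adjusted p = 0.353, 0.155 and 0.175). None of the 5 held a peak in an MBD6-RFP list.

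ACD15 and ACD21 regions avoided protein-coding gene bodies and lay more often in promoters, in other sequence outside genes and in gene-poor parts of the chromosomes. The centres of 16.4% of ACD15 and 17.1% of ACD21 regions fell in a protein-coding gene, against 53.8% and 53.9% of shuffled placements. Within 1 kb upstream of a gene start lay 22.6% and 24.2%, against 13.7% for both. Outside protein-coding genes, pseudogenes and promoters lay 47.22% and 47.95%, against 23.6% for both. The ratios to shuffling were 2 and 2.03 there and 1.65 and 1.77 in promoters. Promoters were thus not favoured over other sequence outside genes. In gene-poor 100 kb bins lay 28.6% and 26.5%, against 17.1% for both. The MBD5/MBD6 regions had 25.0% in gene bodies, 19.6% in promoters and 28.8% in gene-poor bins, against 53.9%, 13.7% and 17.0%. Each of these differences had a permutation p of 0.001 (two-sided, the smallest that 1000 shuffles can give; adjusted p = 0.00106 over 55 tests). Pseudogenes, which in this annotation include transposon genes, took 13.7% of ACD15 and 10.7% of ACD21 regions, above the shuffled 8.87% and 8.84%, but ACD15 without replicate 2 gave 6.20% and ACD21 without replicate 1 gave 7.56%, both below shuffling. The promoter excess of MBD5/MBD6 regions was lost when any overlap was counted (38.9%, permutation p = 0.399) or with promoters of 500 bp (8.51%, p = 0.538).

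MBD6-RFP peaks covered less of the genome in acd15 acd21 than in wild type at both replicate numbers, while their number was higher in the mutant at one and lower at the other. Covered length was 2636 kb and 543 kb in the wild type libraries and 1919 kb and 133 kb in the acd15 acd21 libraries, replicate 1 first, a ratio of mutant to wild type of 0.728 for replicate 1 and 0.244 for replicate 2. Peaks within MBD5/MBD6 regions numbered 2875 and 1176 in wild type and 1892 and 344 in acd15 acd21, ratios of 0.658 and 0.292. The number of all peaks was 3492 in wild type and 3987 in acd15 acd21 for replicate 1, and 1244 and 404 for replicate 2. On the log2 scale covered length was 20.19 ± 1.61 in wild type and 18.94 ± 2.73 in acd15 acd21 (SD, n = 2 each). The differences of -1.25 in log2 covered length and -0.72 in log2 peak number were smaller than the SD within the mutant group, 2.73 and 2.34, and the two-sided exact permutation tests gave p = 0.667 and p = 1, where 2 against 2 libraries cannot go below 0.333. Both values rest on sums over regions called separately in each library, with median peak widths of 635 and 363 bp in wild type and 420 and 282 bp in acd15 acd21, and the authors' filter left 53.0% and 42.9% of the peak numbers in the replicate 1 lists but 96.5% and 93.1% in those of replicate 2.

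**Figure D3:**
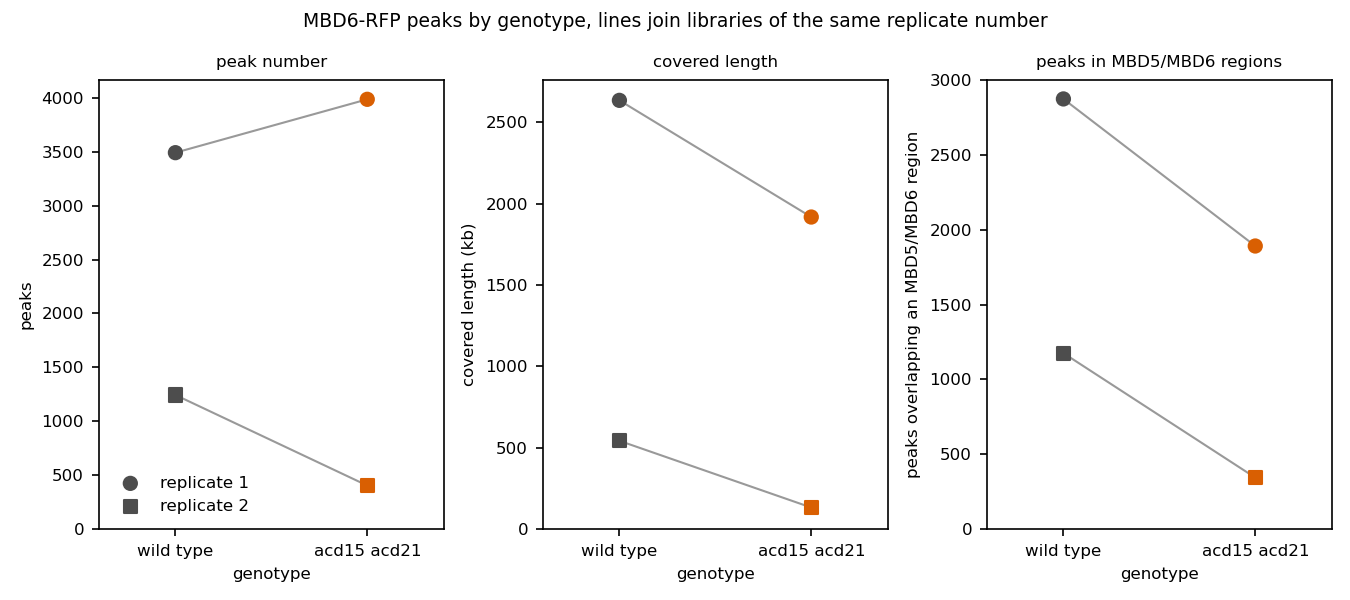
Points give the number of MBD6-RFP peaks, their covered length in kb and the number of peaks in MBD5/MBD6 regions for each library by genotype, with lines joining libraries of the same replicate number. Covered length and peaks in MBD5/MBD6 regions are lower in acd15 acd21 at both numbers, and peak number only for replicate 2.

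Lists with the same replicate number overlapped more than lists of the same genotype. Of the wild type replicate 1 peaks, 53.2% (51.5 to 54.9, exact binomial over peaks) overlapped the acd15 acd21 replicate 1 list and 4.78% (4.10 to 5.54) the other wild type list. Of the wild type replicate 2 peaks, 23.6% (21.3 to 26.1) overlapped acd15 acd21 replicate 2, 15.6% acd15 acd21 replicate 1 and 13.8% (11.9 to 15.8) wild type replicate 1. In turn, 74.3% of the acd15 acd21 replicate 2 peaks overlapped wild type replicate 2 and 5.20% acd15 acd21 replicate 1. Jaccard indices were 0.290 and 0.174 for libraries of the same number, and 0.0229 and 0.00281 for the wild type and the mutant pair. The mean index within genotypes was lower by -0.112 than that between them (one-sided exact permutation p = 1, smallest possible 0.333). All but 2 of the 12 overlaps passed the test against shuffling (permutation p from 0.001 to 0.004, adjusted 0.0015 to 0.0048). Wild type replicate 1 in acd15 acd21 replicate 2 (0.430% against 0.369% by shuffling, permutation p = 0.299) and the reverse (3.71% against 3.13%, p = 0.28) did not pass. When at least 50% of the peak had to overlap, wild type replicate 1 in wild type replicate 2 fell to 0.229% against 0.332% by shuffling.

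Most MBD6-RFP peaks in wild type lay in regions bound by MBD5 or MBD6, 82.3% and 94.5% of them, and in acd15 acd21 47.5% and 85.2%. ACD15 regions held 66.2% and 83.8% of the wild type peaks and 33.3% and 64.4% of the mutant peaks, and ACD21 regions 53.0% and 71.1%, and 24.8% and 51.5%. All 12 shares lay above shuffling (permutation p = 0.001, the smallest possible). The 2055 peaks of acd15 acd21 replicate 1 without a wild type peak of that number stood apart, with 17.5% in MBD5/MBD6 regions and 67.9% centred in protein-coding genes, against 79.4% and 15.2% of the 1932 shared peaks. Shuffled placements gave 13.8% and 54.0% for the whole list of that library. Whether the 2055 peaks are more than background was not tested. For replicate 2 the 104 peaks found only in the mutant had 57.7% in MBD5/MBD6 regions, against 94.7% of the 300 shared ones, and 27.9% centred in protein-coding genes, against 17.0%. The share in MBD5/MBD6 regions differed between genotypes by -22.1 points (88.4 ± 8.63% against 66.3 ± 26.7%, SD, n = 2 each, exact permutation p = 0.667).

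Comparing single genes between the genotypes was limited by how few promoter peaks the libraries of 1 genotype shared. In wild type, 1124 and 263 protein-coding genes had a promoter peak and 60 had one in both libraries; in acd15 acd21 the numbers were 1352, 75 and 4. Of the 60, 4 had none in either acd15 acd21 library, AT5G28660, AT3G29690, AT3G29580 and AT2G16340, none with a symbol. The replicate 1 peaks of the first 3 lay upstream of the gene start, on chromosome 5 at 10681043 to 10682379 and on chromosome 3 at 11542114 to 11544448 and 11396247 to 11397212, with folds of 25.6, 8.60 and 14.4; the first 2 summits lay 1468 and 2122 bp from the start, beyond the promoter and inside AT5G28655 and AT3G29695. At AT2G16340 the replicate 2 peak had its summit in a coding exon, on chromosome 2 at 7073123 to 7073418. No gene had a promoter peak in all 4 MBD6-RFP libraries, and of the 4 genes shared by the acd15 acd21 libraries AT4G06655 alone had none in wild type, with its peak on chromosome 4 at 3882193 to 3882443 and the summit inside AT4G06670. The 4 wild type peaks named lay in ACD15, ACD21 and MBD5/MBD6 regions, and that of AT4G06655 in an MBD5/MBD6 region only.

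MBD6-RFP peaks of both genotypes were frequent in gene-poor bins and at pseudogenes. Gene-poor bins held 43.6% and 54.7% of the wild type and 36.7% and 60.2% of the acd15 acd21 peaks, against 17.0% to 17.3% by shuffling, and pseudogenes 24.9% and 42.4%, and 22.3% and 52.2%, against 8.81% to 8.96% (permutation p = 0.001 each, the smallest possible). Protein-coding gene bodies held 14.5% and 12.7% of the wild type peaks and 42.4% and 19.8% of the acd15 acd21 peaks, against 53.8% to 54.0% by shuffling. The difference between genotypes was 17.5 points. Promoters held 15.1% and 10.2%, and 7.37% and 4.46%, a difference of -6.72 points. Both differences had the same sign for replicate 1 (27.9 and -7.69 points) and replicate 2 (7.10 and -5.75 points) and the smallest p of the exact permutation test, 0.333, so neither can pass 0.05. Pseudogene and gene-poor shares differed in opposite directions for the replicate numbers (exact permutation p = 1 for both). The wild type promoter share of replicate 1 was above shuffling (13.7%, permutation p = 0.015) and that of replicate 2 below it (p = 0.001); the first was below shuffling when any overlap was counted or with 500 bp promoters.

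The peaks of all 3 proteins were richer in CG dinucleotides than placements of the same width on the same chromosomes. Merged ACD15 regions had 3.13 ± 1.70 CG per 100 bp (SD over regions), ACD21 regions 3.63 ± 1.73 and MBD5/MBD6 regions 3.00 ± 1.47, against 2.34 for width-matched placements, ratios of 1.34, 1.55 and 1.28. MBD6-RFP peaks had 3.40 and 6.73 in wild type and 4.25 and 7.20 in acd15 acd21. All had a permutation p of 0.001 (two-sided, the smallest 1000 shuffles can give). The densities of the genotypes differed by 0.662 CG per 100 bp (5.06 ± 2.35 against 5.73 ± 2.09, SD, n = 2 each, exact permutation p = 0.667). Within replicate numbers the mutant was higher by 0.848 and 0.476. With a 200 bp window at the summit, which changes both width and position, the genotype difference was 0.0856. The ratios to shuffling were then 2.12 in wild type and 2.37 in acd15 acd21 for replicate 1. For replicate 2 they were 3.46 and 3.28, so the mutant was not higher at both numbers. The GC content of MBD6-RFP peaks was 37.6% and 49.0% in wild type and 42.6% and 54.5% in acd15 acd21, higher by 4.97 and 5.45 points within replicate numbers (exact permutation p = 0.667). Ratios of CG density to width-matched placements were 1.45 and 2.87 in wild type and 1.81 and 3.08 in acd15 acd21. To GC-matched placements they were 1.315 and 1.254, and 1.225 and 1.085. Most of the CG excess of the replicate 2 lists was thus matched by GC content. The ratio of CG density to GC-matched placements was lower in the mutant by -0.130 (exact permutation p = 0.333), the reverse of the direction for the density itself.

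**Figure D4:**
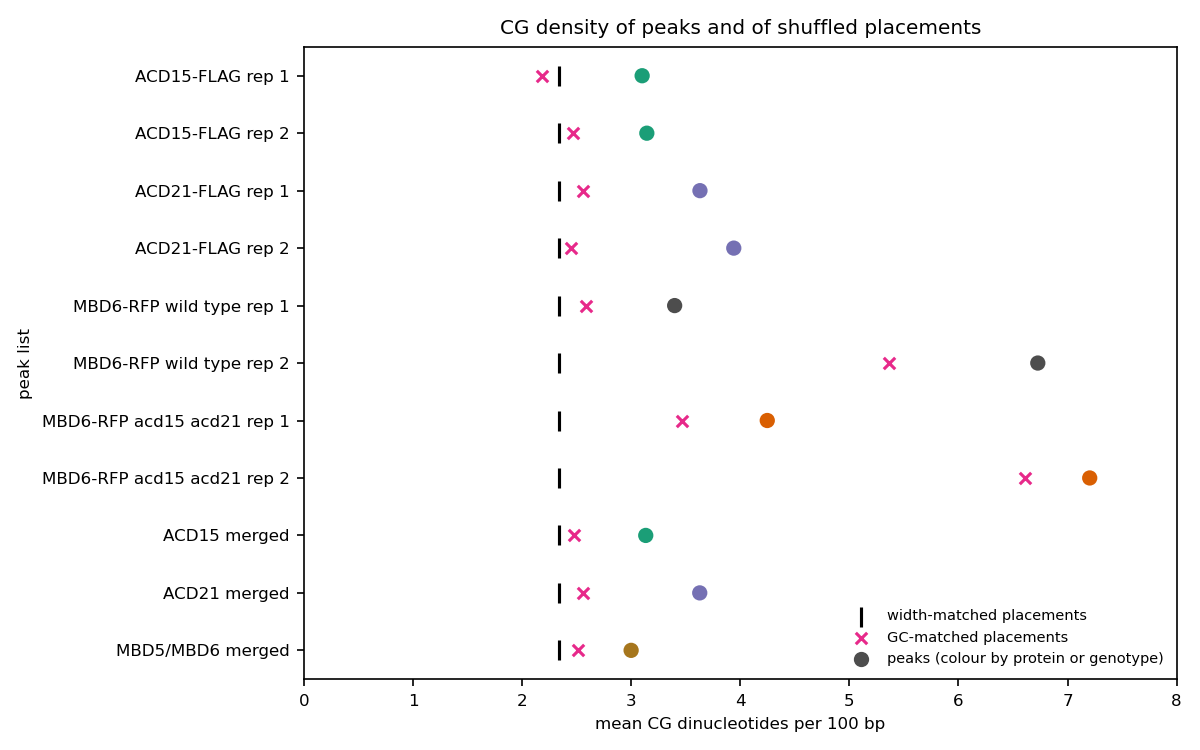
Filled circles give mean CG dinucleotides per 100 bp in the peaks of each list, vertical ticks the mean of width-matched placements and crosses that of placements matched on GC content. Every list lies above both, and the MBD6-RFP replicate 2 lists lie highest, at 6.73 and 7.20. Their GC-matched placements gave 5.36 and 6.61.

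Wild type MBD6-RFP peaks that had a counterpart in an acd15 acd21 list stood higher in their own list than those without one. In replicate 1, 1859 retained and 1633 lost peaks had mean percentiles of 58.1 and 40.8, a difference of 17.2 (p = 1e-05, the smallest 100000 permutations can give), and in replicate 2, 479 and 765 peaks had 53.5 and 47.9, a difference of 5.65 (p = 0.00081, adjusted 0.00114 over 24 tests). An overlap of 1 bp is met more easily by wide peaks, and the retained ones were wider (869 against 625 bp and 493 against 401 bp); when 50% of the peak had to overlap, the percentile differences were 11.2 (permutation p = 1e-05) and 3.17 (p = 0.0666). In replicate 1 they had more CG per 100 bp, 3.59 against 3.18, and a higher GC content, 38.8% against 36.2% (permutation p = 1e-05 each), and in replicate 2 the means of 6.64 and 6.78 did not pass the test (p = 0.174). GC content in replicate 2 was lower in retained peaks, 47.7% against 49.8%, but higher, 52.0% against 48.1%, when only the acd15 acd21 list of the same number was used (permutation p = 1e-05 each). These tests permute peaks, which are not independent replicates. Without acd15 acd21 replicate 1 the percentile difference of wild type replicate 1 was 7.22 over 15 retained peaks (permutation p = 0.338), and without acd15 acd21 replicate 2 that of wild type replicate 2 was 4.20 (p = 0.0647) and its CG difference -0.497 (p = 0.00014).

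The MBD5/MBD6 regions occupied by each library differed in GC content, a comparison chosen after the replicate overlaps had been seen. Wild type MBD6-RFP replicate 1 had a peak in 38.2% of the middle GC quintile (mean GC 34.8%) and in 13.2% of the highest (47.6%), and replicate 2 in 7.93% and 16.7%. For acd15 acd21 the shares were 22.0% and 16.9% in replicate 1 and 1.85% and 9.17% in replicate 2. ACD15 replicate 1 occupied 65.1% of the second quintile (30.4%) and 9.07% of the highest, and ACD21 replicate 1 63.6% and 27.4%. These shares describe single libraries and were not tested.

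**Figure D5:**
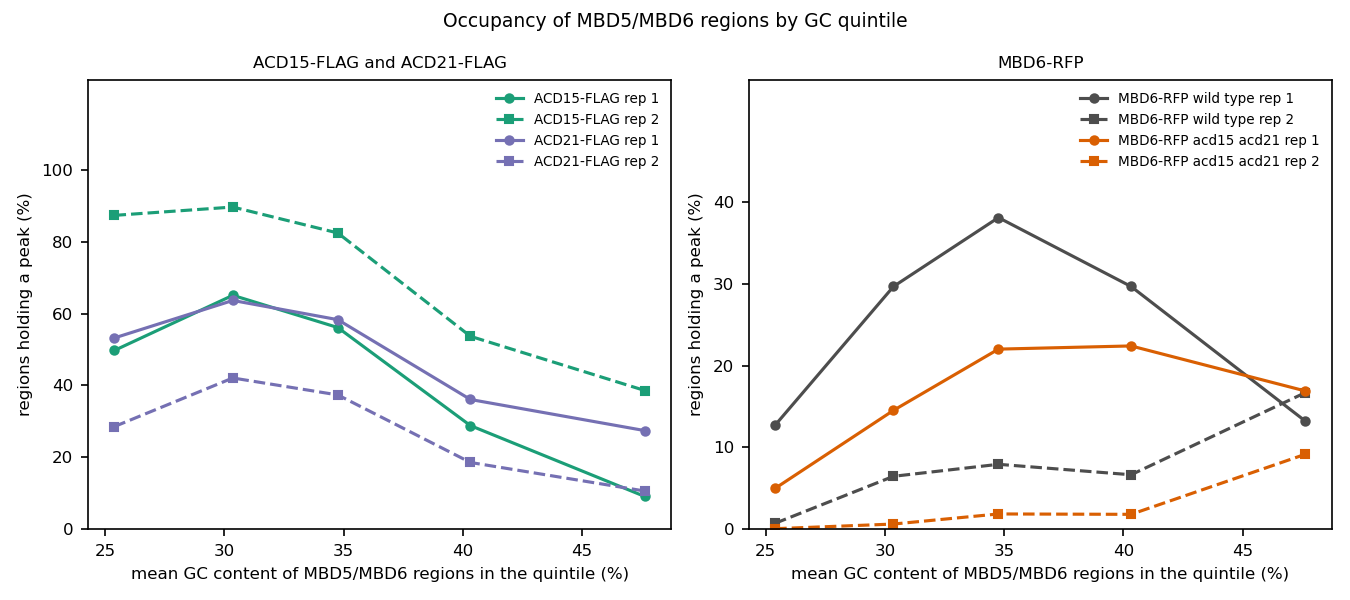
Lines give, for each library, the percent of MBD5/MBD6 regions holding a peak in each GC quintile, plotted at the quintile's mean GC content in percent. FLAG lists fall from the second to the highest quintile, and the MBD6-RFP replicate 2 lists reach their highest shares, 16.7% and 9.17%, in the last.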

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

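The tests of a shallower sample, of background peaks, of GC content as the whole cause of low sharing, and of CG density in replicate 1 alone, and the GC-matched placements, were chosen only after the results were seen. The MBD5/MBD6 list held 32 regions on the mitochondrial genome, 55150 bp in all, outside the nuclear regions compared; none of them came from both parent lists, and the FLAG and RFP lists held none.

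The wild type MBD6-RFP replicates shared few peaks, and the design offers no biological explanation to test. A shallower sample of the same sites would put most replicate 2 peaks inside replicate 1, but 13.8% of them overlapped it, and background outside known sites is argued against by the 94.5% of them in MBD5/MBD6 regions. Within deciles of region GC content, wild type and acd15 acd21 of replicate 1 shared 2.96 times the regions independence gives (95% interval 2.85 to 3.05). The wild type replicates shared 1.31 times (1.19 to 1.43). This argues against the GC content of whole MBD5/MBD6 regions as the only cause. It does not cover GC content at the peaks, which was 37.6% in wild type replicate 1 and 49.0% in replicate 2. The compared pair has the same replicate number and would share a GC bias of that number. The ratio of the wild type replicates, planned as the test of any GC effect, decides nothing. It was above 1 without GC deciles too (1.25), so part or all of the low sharing could still follow GC content at the peaks. Open too is a difference in library preparation or filtering between replicate numbers, since 53.0% and 42.9% of the peak numbers were left in the replicate 1 lists and 96.5% and 93.1% in those of replicate 2.

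MBD6-RFP peaks covered less sequence in acd15 acd21 at both replicate numbers, and the genotype is the biological explanation the design gives, untested against depth. Lower depth or signal in the mutant libraries predicts that retained peaks rank at least 10 percentile points above lost ones; the difference was 17.2 in replicate 1 and 5.65 in replicate 2, which meets it in one only, and 11.2 and 3.17 when 50% of the peak had to overlap, so depth and genotype cannot be told apart. Loss at sites of high CG density predicts denser lost peaks. In replicate 1 the retained peaks were the denser ones, by 0.410 CG per 100 bp and by 1.23 in a 200 bp window at the summit. They were also higher in GC content (38.8% against 36.2%), and CG observed over expected was 0.981 against 1.00 (permutation p = 0.0506). Calls were thus not lost mainly at dense sites there. A peak counts as retained while it is still called, and retained peaks ranked higher and were wider. The split therefore cannot show whether signal fell at dense sites. In replicate 2 the density difference was -0.133 and not past its test. CG observed over expected was 1.24 in retained peaks and lower in lost ones, but 1.03 against 1.20 with the mutant list of the same number (permutation p = 1e-05 each). The explanation stays open in both replicates.

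The CG density of ACD15 and ACD21 regions above width-matched placements might follow from GC content alone. Against GC-matched placements the ratios were 1.26 and 1.42, which argues against GC content as the whole cause. Methylation itself was not measured here, so whether the regions hold methylated CG sites stays open.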

How the results depend on the processing

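The GC-matched placements, the count within MBD5/MBD6 regions and the highest peak number were chosen after seeing the data. Of 236 alternatives over 66 results, 38 compare the genotypes, where no p can pass 0.05. Of these, 33 kept direction and 5 reversed. The Jaccard index within minus between genotypes cannot pass 0.05 either but is counted with the others. Of the other 198, 179 kept direction and, where tested, side of the threshold, 7 lost it, 1 gained it, 1 moved and 10 reversed. All 12 for FLAG replicate overlap and all 42 for overlap of the merged sets kept both. Some outcomes were fixed in advance. The union of replicates repeats the merged lists, and shuffling within gene-poor or other bins changes only the shuffled value. Among the 38, a replicate block leaves the mean difference as it was. Where no reason is given, the cause was not tested. Requiring an overlap of 50% of the peak took wild type replicate 1 in replicate 2 to 0.229% (shuffled 0.332%) and the percentile difference of wild type replicate 2 to 3.17 (permutation p = 0.0666). The upper 50% of each list gave pseudogene shares of 6.46% for ACD15 and 6.54% for ACD21, below shuffling, a promoter share of 15.4% for wild type replicate 2, above it but not past the test (13.7%, permutation p = 0.186), and a genotype difference of 6.45 points in gene-poor bins. Any overlap gave promoter shares of 38.9% for MBD5/MBD6 and 27.5% for wild type replicate 1, and promoters of 500 bp gave 8.51% and 6.87%. The genotype difference in CG density, as a ratio to GC-matched placements, was -0.130. The shorter gene window left 0 gene list tests past the threshold (2 before), with 47.6% for both ACD15 (Fisher exact test, adjusted p = 0.0703) and MBD5/MBD6 (0.206). Leaving out replicates, which leaves 1 library per group and no test between genotypes, gave log2 peak number differences from -1.62 to 0.19, recovery of wild type replicate 1 in either mutant list from 0.430% to 53.2%, percentile differences from 7.22 to 17.2 (wild type replicate 1) and from 4.20 to 4.89 (replicate 2), CG differences of replicate 2 from -0.497 to 0.158, pseudogene shares from 6.20% to 13.8% (ACD15) and from 7.56% to 10.7% (ACD21), and genotype differences from -2.67 to 9.78 points for pseudogenes and from -6.92 to 5.49 for gene-poor bins. The replicate numbers are not said to mark a shared day, and 2 pairs are too few to show it; with a replicate block the difference was -0.72 for log2 peak number (exact sign-flip p = 1) and -1.25 for log2 covered length (p = 0.5, the smallest possible), so no call could change with the block. By number, the mean Jaccard index within pairs exceeded that between them by 0.217 (one-sided exact p = 0.333, the smallest possible). Peak lists carry no depth, so none of these values can be weighed by it. Not run were the transposon superfamily alternatives, the upper 50% of the MBD5/MBD6 list, which has no score, and Jaccard indices without a replicate. The organelle alternative was not run either, as only the MBD5/MBD6 list holds such regions.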

Other observations

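The comparisons in this part were chosen after the overlaps had been seen. ACD15 regions shared with ACD21 were the higher-ranking ones. The merged ACD21 list was the shorter one (6803 against 11101 regions), so list length could give this too. The 6087 ACD15 regions that overlapped ACD21 had a mean percentile of 67.1, against 28.3 for the 5014 without ACD21, each region taking the higher of its percentiles in the 2 replicate lists, which favours regions found in both, and the share with ACD21 was 15.6%, 33.9%, 72.4% and 99.0% from the lowest to the highest of 4 classes 25 percentile points wide. Regions with ACD21 held 3.24 CG per 100 bp against 3.01, and within each class the density was also higher with ACD21, at 5.36 against 3.60 in the lowest and 2.83 against 1.79 in the highest, where 27 regions lacked ACD21. Of the regions without ACD21, 89.2% still lay in MBD5/MBD6 regions, against 98.1% of those with it (p = 0.0001 for each mean, the smallest that 10000 permutations of regions can give).

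The shares of pseudogenes, transposon genes among them, and of protein-coding genes with a peak were counted for the 3 merged and 4 MBD6-RFP lists. A peak was counted from 1 kb upstream of the start to the gene end, so the shares include upstream peaks and depend on gene length. They were not tested, and 926 pseudogenes annotated as transcribed were left out. Of the other 3917, 39.7% held an ACD15 region, 24.3% an ACD21 region and 59.7% an MBD5/MBD6 region, and of 27444 protein-coding genes 20.1%, 12.9% and 26.1%. MBD6-RFP peaks were found at 29.8% and 12.3% of pseudogenes in wild type and 28.0% and 5.72% in acd15 acd21, and at 5.70% and 1.26%, and 8.92% and 0.503%, of protein-coding genes. The transcribed pseudogenes held ACD15 regions at 34.7%, and acd15 acd21 replicate 1 peaks at 8.53%, below the share of protein-coding genes. Among 625 tRNA genes, 9.28% held an ACD15 and 4.32% an ACD21 region, and acd15 acd21 replicate 1 had a peak at 6.08%, against 2.40% for wild type replicate 1; in replicate 2 the shares were 0.16% and 0.32%. By peak centres, the share at pseudogenes was below shuffling in ACD15 replicate 1 (6.20% against 8.84%, permutation p = 0.001) and ACD21 replicate 2 (7.56% against 8.78%, permutation p = 0.011), and above it in the other FLAG libraries.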
